A study of Mus musculus with 8 samples.

How the data were processed

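Total RNA of leukemia cells from 8 transgenic mice was measured on Affymetrix Mouse Exon 1.0 ST arrays, 1 array per mouse, with 4 mice labelled TCL1 and 4 labelled ROR1xTCL1. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase, and biotin-labelled cDNA was made with a whole-transcript kit. The series text states that no technical replicates were made, so the spread within a group is that between animals.

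The deposited data are 2 tables. The first holds 1 log2 value per probe set for 1236087 probe sets, and per the labels these are RMA values (background-corrected, quantile-normalized and summarised over probes) made with the Bioconductor package oligo. R 2.15.1 is named in the submitters' processing notes. The second holds 1 value per gene in 16495 rows. Its scale is not stated; the values were taken as log2 from their range (0.89 to 12.64), and every gene-level log2 difference rests on this. The series text names the Affymetrix Exon Array Computational Tool for the array data, and the step from probe sets to genes is not given in the sources used here. RMA and the equal distributions of the arrays remove any difference in the total signal between groups, so all values are relative to the other genes of the same array.

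The columns of the probe set table carry the samples' own identifiers. The columns of the gene table show the genotype of each array but not which sample it is, so they were used as unnumbered members of their group and are called arrays a to d of TCL1 and of ROR1xTCL1; probe set columns are called replicates 1 to 4. No label ties a letter to a number, and none was matched. As a check of this reading, each of the 8 gene table columns correlated best with a probe set column of its own group across 15640 genes centred on their means, at r of 0.826 to 0.912, with at most 0.273 for any other column. Genes are not independent replicates, and this comparison was used to assign nothing. No column of sample values was left unused.

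In the gene table, 4 rows named only by a number were left out and 72 names found on several rows were averaged. 43 of these 72 differed by more than 1 log2 unit between their rows. This left 16419 genes, of which 14742 matched a current mouse symbol in the RefSeq gene table of assembly GRCm38.p6, 1441 matched a synonym, and 236 kept the deposited name. Of the probe sets, 321091 had 1 gene symbol in the platform annotation, 7796 had several and 907200 were unnamed here; no gene was named from a probe set with several. No genome build was given for the values, so no coordinates are printed.

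Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior, 2-sided), ROR1xTCL1 minus TCL1, with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p under 0.05. No filter on dim genes was used. Probe sets were tested in the same way. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists tested. 39 lists with 727 entries in all were written before the data were examined; 643 entries were measured, and the 38 lists with at least 5 measured members were tested. A list score is the mean, over a list's genes, of the log2 value minus the gene's mean over the 8 arrays. Exact 2-sided permutation tests over the 70 orderings of 4 against 4 arrays cannot give a p below 0.0286. Intervals are 95% intervals of the limma fit. The number of arrays limits the precision: the median half-width of the interval of a gene's log2 difference was 0.34.

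The genes named in the text follow a rule fixed before the data were examined. It takes the 12 largest increases and 12 largest decreases past the threshold with no overlap between the groups' arrays. Where fewer pass, it takes the genes of smallest unadjusted p with an absolute log2 difference of at least 0.5 and no overlap, which miss the threshold. Predicted genes and immunoglobulin or T cell receptor segments are passed over in this part; there were 0 such genes among those eligible. The rule also names up to 4 members of each called list, up to 3 of any other list, and Ror1, Ror2, the Tcl1 family, Xist and the Y-linked genes. Genes named outside it are said to be chosen after their values were seen.

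The gene test was tested on simulated data. With 200 genes changed per run in the deposited values of the 16419 genes, 69.3% of 2-fold, 95.8% of 4-fold and 98.2% of 8-fold changes were called, with 4.4 false calls per run over 10 runs. With only 9 genes changed per run, 16.7% of 2-fold, 86.7% of 4-fold and 96.7% of 8-fold changes were called. Each simulated change was the same step on all 4 ROR1xTCL1 arrays. These shares therefore do not cover changes whose size varies between animals. In 10 simulated runs of independent genes, camera called a list shifted by 0.5 log2 units in 10 runs and called 0 of 380 unshifted lists. These list simulations hold no correlation between genes.

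Alternatives fixed before the data were examined were gene values made as the mean of a gene's probe sets, a further quantile normalization, centring on array medians, leaving out features under the 40th percentile of mean value, the replicate number as a block, eBayes with trend and robust, array weights, other thresholds, camera with an estimated correlation, fry, and leaving out each array in turn. The replicate block on gene values, an estimated correlation on gene values made from probe sets, the Y-linked genes as a covariate, leaving out TCL1 arrays a and c together (with a preset and an estimated correlation) and the permutation test of list scores were chosen after seeing the data.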

Results

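Gene expression was measured in leukemia cells of 8 mice. 4 mice carried the TCL1 transgene alone. This is an oncogene placed under the immunoglobulin heavy chain enhancer, and such mice develop a B cell leukemia resembling human chronic lymphocytic leukemia. The 4 ROR1xTCL1 mice carried a ROR1 transgene as well, which encodes a surface receptor for Wnt5a found on human chronic lymphocytic leukemia cells. The comparison asks how leukemias that arose with both transgenes differ in expression from those that arose with TCL1 alone. Median log2 gene values lay between 5.03 and 5.09 on the 8 arrays.

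Gene values of arrays of the same group correlated at a mean r of 0.975 over 12 pairs, and those of different groups at 0.977 over 16 pairs. The first principal component held 27.5% of the variance and placed TCL1 array d (32.7) and ROR1xTCL1 array b (27.3) at the end opposite to ROR1xTCL1 array a (-28.0) and TCL1 array a (-23.2). The second, with 18.9%, set TCL1 array c (-28.8) and ROR1xTCL1 arrays c (-23.0) and d (-9.17) apart from the other 5. These 3 arrays had the highest values of the Y-linked genes. Ddx3y was at 7.29, 7.70 and 8.15 on them and at 2.42 to 2.88 on the others, and Kdm5d at 6.59, 6.79 and 6.12 against 2.54 to 2.94. Xist, the RNA that silences an X chromosome in females, averaged 3.55 on TCL1 replicate 3, 2.95 on ROR1xTCL1 replicate 3 and 3.48 on ROR1xTCL1 replicate 4, and 11.2 to 11.4 on the other 5 over its 12 probe sets. By Xist, TCL1 replicate 3 and ROR1xTCL1 replicates 3 and 4 read as male and the other 5 as female. The groups were therefore not balanced for sex.

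Ror1 was examined first, as a check of the labels. Of the 13 probe sets annotated to mouse Ror1, 3 were far higher in every ROR1xTCL1 array than in any TCL1 array. Probe set 5507566 read 9.26 ± 0.93 (SD, n = 4) in ROR1xTCL1 and 5.96 ± 0.25 (SD, n = 4) in TCL1, a log2 difference of 3.30 ± 0.41 (SE). Probe set 5612493 differed by 3.58 ± 0.57 (SE), from 4.86 ± 0.70 to 8.44 ± 1.30 (SD, n = 4 each), and probe set 5320447 by 2.27 ± 0.37 (SE), from 2.0 ± 0.52 to 4.27 ± 0.66 (SD, n = 4 each). The TCL1 mean of 5320447 lies under the first quartile of all probe sets (2.18 to 2.24 on the 8 arrays) and is not shown to exceed background, so its difference is read as a lower bound. With limma p-values adjusted over the 13 Ror1 probe sets alone, these 3 rose (adjusted p = 5.74e-05, 0.000289 and 0.000289) and probe set 4375365 fell by 0.78 ± 0.27 (adjusted p = 0.0454). The other 9 did not pass, and the median difference over all 13 was 0.50. Adjusted over all 1236087 probe sets, none of the 13 passed (adjusted p = 1.0), although 5507566 ranked 3rd of them by p. ROR1xTCL1 replicate 1 had the lowest values of its group at 5507566 (7.92), 5612493 (6.63) and 5320447 (3.65). The sources used here do not say from which species the ROR1 transgene comes, and mouse probes need not read all of it.

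**Figure D1:**
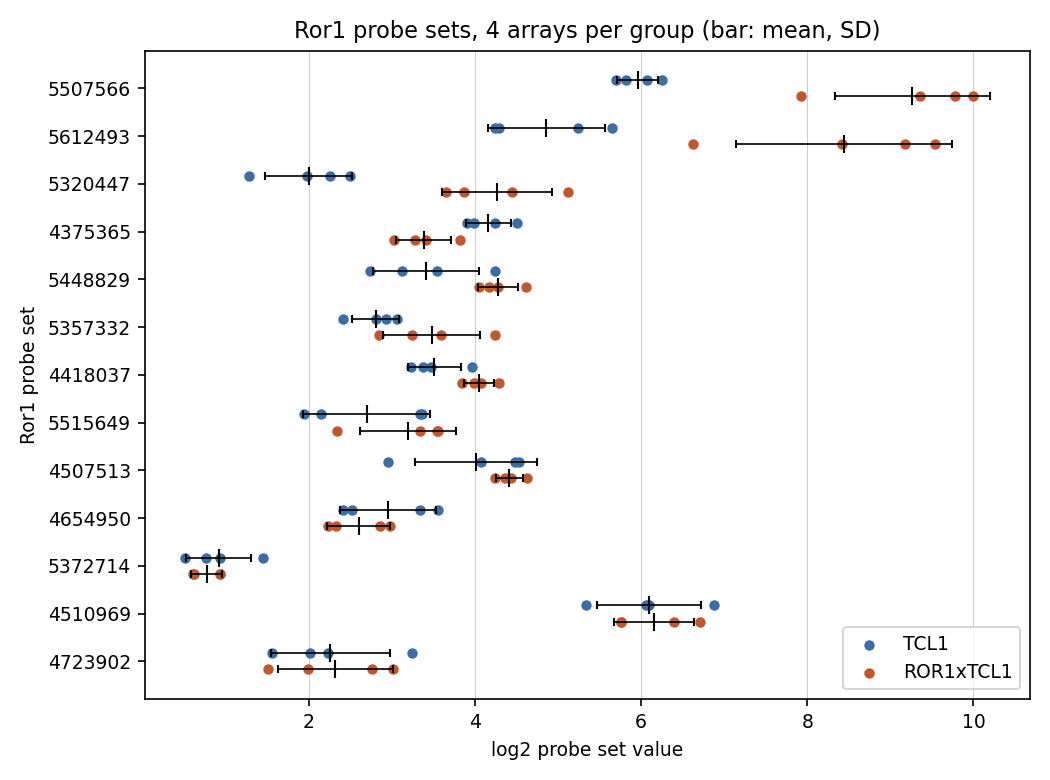
Log2 values of the 13 Ror1 probe sets (horizontal axis) on the 4 TCL1 and 4 ROR1xTCL1 arrays, 1 point per array, with the group mean and SD as bars. At probe sets 5507566, 5612493 and 5320447 all 4 ROR1xTCL1 arrays lie above all 4 TCL1 arrays.

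At gene level, Ror1 was 4.41 ± 0.34 in ROR1xTCL1 and 3.77 ± 0.17 in TCL1 (SD, n = 4 each), with no overlap between the groups. This difference of 0.64 ± 0.18 (SE) missed the threshold (limma adjusted p = 1.0). Ror2, the other member of the receptor family, differed by -0.09 ± 0.22 (SE). Mouse Tcl1 read 3.58 ± 0.25 in ROR1xTCL1 and 3.59 ± 0.31 in TCL1 (SD, n = 4 each), below the median gene. Both means lay within the range of the first quartiles of the arrays (3.52 to 3.71). Mouse probes need not read the TCL1 transgene, so these low values do not show that it is silent. The mouse Tcl1b genes measured (Tcl1b1 to Tcl1b5) read 1.69 to 3.50 on average in each group, and their differences ranged from -0.19 to 0.22 with 0 past the threshold.

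Across the transcriptome, no gene passed the threshold between ROR1xTCL1 and TCL1 leukemias. Of 16419 genes, 0 were higher and 0 lower at an adjusted p under 0.05 (limma; smallest adjusted p = 1.0), and 268 (1.63%) had an unadjusted p under 0.05, where 821 would be reached by chance with independent genes. The values of 180 genes (1.10%) did not overlap between the groups, where chance gives 2.86%. The largest mean differences were those of Il12a, a subunit of interleukin 12 (-1.91 ± 0.93 SE), and Trim29 (1.84 ± 1.56 SE). Il12a is named after its values were seen, and its groups overlapped: ROR1xTCL1 array a read 8.79, above TCL1 arrays a (6.35) and b (7.66). The Trim29 difference came from ROR1xTCL1 array a alone, at 11.61 against 3.72 to 4.29 on the other 7.

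All 19 genes named by the rule for the smallest p missed the threshold. Among the 7 higher in ROR1xTCL1 were Gjd3, a gap junction protein, at 0.79 ± 0.16 (SE), Ror1, Dpf3, a chromatin remodelling subunit, at 0.54 ± 0.17, the homeobox gene Rhox6 at 0.53 ± 0.19, and the olfactory receptor genes Olfr1445 (0.80 ± 0.23), Olfr401 (0.66 ± 0.17) and Olfr201 (0.58 ± 0.26). Among the 12 lower was Ccl17, a chemokine that attracts T cells through Ccr4, at 5.59 ± 0.34 in ROR1xTCL1 and 6.99 ± 0.73 in TCL1 (SD, n = 4 each), a difference of -1.39 ± 0.34 (SE). The cytochrome P450 gene Cyp2c40 differed by -1.57 ± 0.30, Stard6, of a lipid transfer family, by -1.04 ± 0.25, Lrrtm2, a synaptic adhesion protein, by -0.92 ± 0.18, the acyl-CoA thioesterase Acot6 by -0.92 ± 0.15, Xkr6 by -0.73 ± 0.16 and Lce1f by -0.56 ± 0.14 (SE). The remaining 5 were the olfactory receptor genes Olfr1196 (-1.14 ± 0.24), Olfr1126 (-0.77 ± 0.14), Olfr1112 (-0.68 ± 0.10), Olfr615 (-0.61 ± 0.11) and Olfr340 (-0.55 ± 0.13). 17 of the 19 averaged under 5 on the log2 scale, and their median of 3.54 lay below the 5.07 of all genes, so most of these differences are between dim signals. No background level was used here, and signals under the first quartile of all genes (3.52 to 3.71 on the 8 arrays) are not shown to exceed it. For Olfr1445, Olfr201, Olfr1112, Olfr1126 and Olfr340 the means of both groups lay under 3.52, so the sizes of their differences are uncertain. For Olfr401, Acot6, Cyp2c40, Olfr1196, Xkr6 and Stard6 the lower group's mean did, so the sizes of these differences are uncertain as well. Of all 144 named genes, both means lay under it for 17, which include Apcdd1, Fdps and the Tcl1b genes, and the lower mean alone for 8, which include Ccr6. With gene values made as the mean of a gene's probe sets, 18 of the 19 were measured and 13 had an unadjusted p under 0.05 by limma. The differences of 4 were then under 50% of those above: Acot6 at -0.32 ± 0.12, Stard6 at -0.24 ± 0.19, Lrrtm2 at -0.21 ± 0.21 and Lce1f at -0.05 ± 0.13 (SE).

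**Figure D2:**
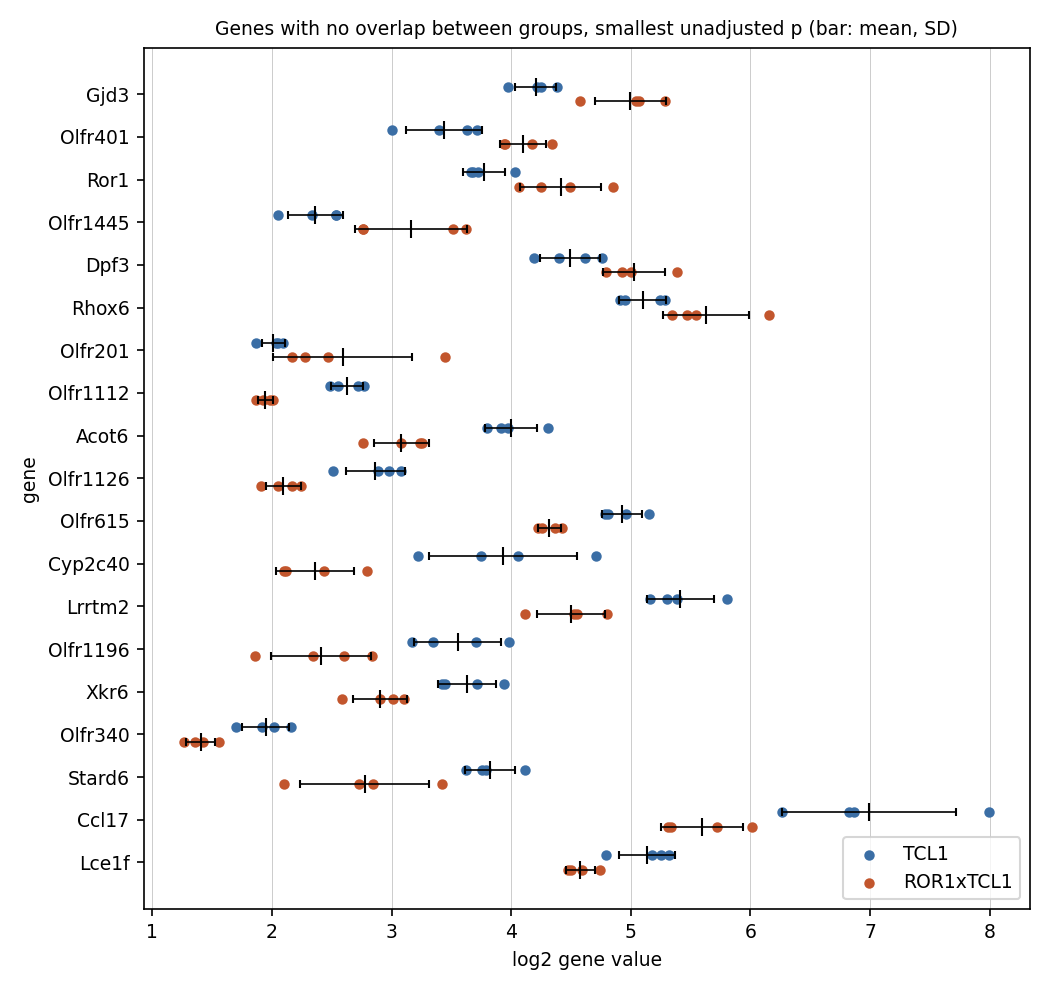
Log2 gene values (horizontal axis) of the 19 genes named for their small unadjusted p, with 4 TCL1 and 4 ROR1xTCL1 arrays as points and the group mean and SD as bars. None overlapped between the groups and none passed the threshold; Ccl17 is the brightest, at 6.99 in TCL1.

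Neutrophil and granulocyte precursor markers were the list most shifted, towards lower values in ROR1xTCL1. All 15 measured members were lower on average, by a median of 0.86 log2 units, although 0 passed the threshold over all genes and 0 when adjusted over the list alone. Cebpe, a transcription factor of granulocyte maturation, read 4.63 ± 0.26 in ROR1xTCL1 and 5.42 ± 0.68 in TCL1 (SD, n = 4 each). The granule proteases Ctsg and Elane differed by -1.14 ± 0.80 and -0.99 ± 0.69 and Mmp9 by -0.85 ± 0.51 (SE). The list was called by camera with a preset correlation (adjusted p = 0.00029) but not with an estimated correlation (adjusted p = 0.914). The list score was high on TCL1 arrays a (2.70) and c (1.26), while TCL1 arrays b (-1.17) and d (-1.11) lay below all 4 ROR1xTCL1 arrays (-0.74 to -0.13). TCL1 array a also had the highest monocyte (0.92), T cell (0.60), natural killer (0.56) and dendritic cell (0.38) scores of the 8 arrays, and TCL1 array c read -0.06, -0.09, 0.22 and -0.20 for these. Without TCL1 array a the call ended (adjusted p = 0.716), as it did without TCL1 array c (adjusted p = 0.133). Without both, chosen after seeing the data, the list was higher in ROR1xTCL1 with a preset correlation (adjusted p = 3.22e-14), and with an estimated correlation it missed the threshold (adjusted p = 0.57). Its estimated inter-gene correlation over the 8 arrays was 0.945, far from the preset 0.01.

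Proliferation genes lay slightly higher on average in ROR1xTCL1, with overlap between the groups' arrays. In the cell cycle and mitosis list 21 of 23 measured genes were above 0, with a median log2 difference of 0.20. Foxm1, a transcription factor of G2 and M phase genes, differed by 0.30 ± 0.21, the topoisomerase Top2a by 0.32 ± 0.29 and the survivin gene Birc5 by 0.33 ± 0.29 (SE). In the DNA replication list 20 of 23 were above 0, with a median of 0.09; Uhrf1, which recruits the maintenance DNA methyltransferase, differed by 0.49 ± 0.34 and the polymerase subunit Pola1 by 0.25 ± 0.17 (SE). Both lists had 0 members past the threshold, over all genes or adjusted over the list alone. Camera with a preset correlation called both (adjusted p = 0.00545 and 0.0244), and neither call held with an estimated correlation (adjusted p = 0.914 for each). The estimated inter-gene correlations were 0.764 and 0.618, so the members of a list are far from independent. Their list scores had exact permutation p = 0.571 and 0.543. TCL1 array c scored 0.33 and 0.35, above ROR1xTCL1 arrays b, c and d. ROR1xTCL1 array a had the highest score of both (0.58 and 0.36) and also the highest erythroid marker score, at 1.80 against at most 0.45 on the other 7. Without that array the calls ended (adjusted p = 0.994 for each). They ended likewise without TCL1 array b (adjusted p = 0.378 for each), without TCL1 array d (adjusted p = 0.782 and 0.945) and without ROR1xTCL1 array d (adjusted p = 0.114 and 0.12).

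Growth and secretory genes were the other 2 lists called. In the MYC and ribosome biogenesis list 15 of 17 genes were above 0, with a median of 0.05; Cad, a pyrimidine synthesis enzyme, differed by 0.24 ± 0.13 and Nop58 by 0.17 ± 0.12 (SE). In the unfolded protein response list 17 of 20 were above 0, with a median of 0.10. The endoplasmic reticulum proteins Pdia6 and Sdf2l1 differed by 0.48 ± 0.31 and 0.50 ± 0.42, and the transcription factor Atf4 by -0.32 ± 0.29 (SE; -0.12 ± 0.25 with gene values made from probe sets). No member of either list passed the threshold, over all genes or adjusted over the list alone. Camera gave adjusted p = 0.0411 and 0.0443 with a preset correlation and adjusted p = 0.914 for each with an estimated correlation. ROR1xTCL1 array d, with the highest unfolded protein response score (0.55), also had the highest plasma cell score (1.04), and without it neither list was called (adjusted p = 0.12 and 0.885). The MYC call also ended without TCL1 array a or d or ROR1xTCL1 array a or b, and the unfolded protein response call without TCL1 array b, c or d or ROR1xTCL1 array a.

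**Figure D3:**
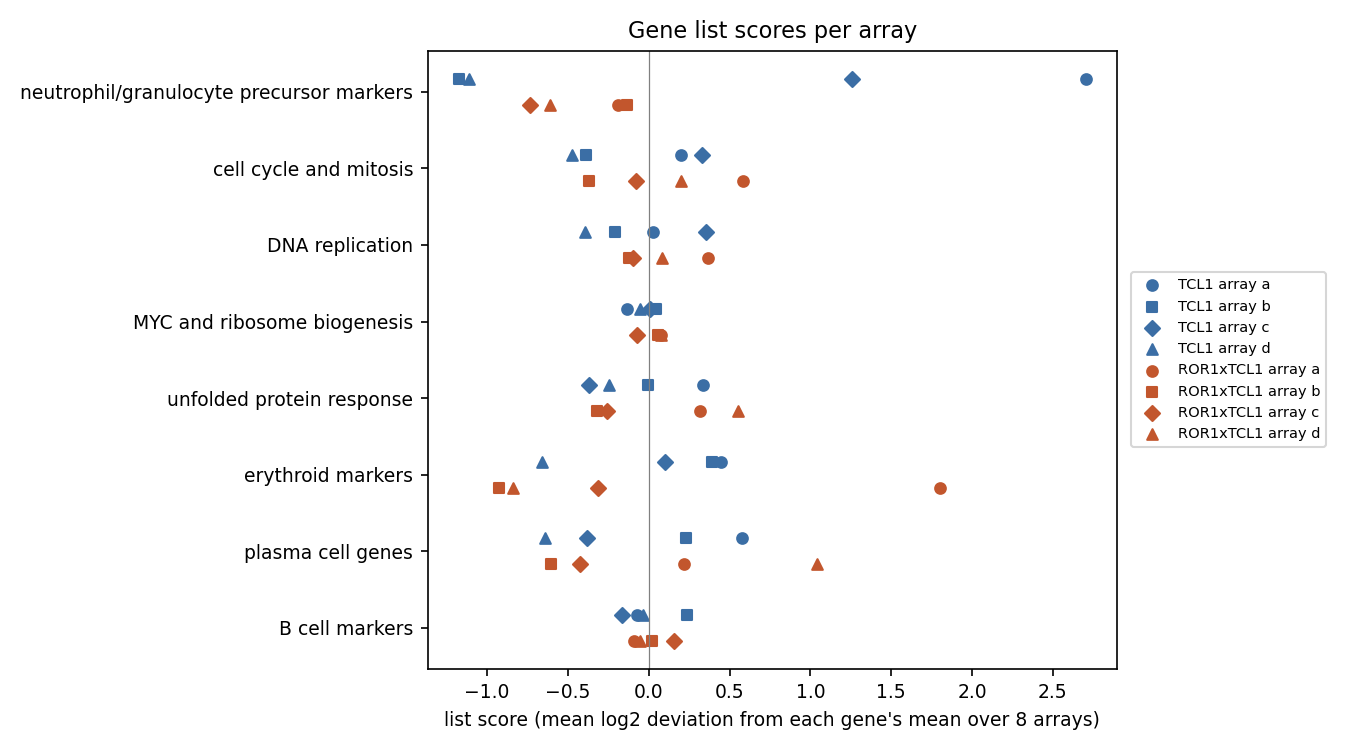
Scores of 8 gene lists on each array (horizontal axis, mean log2 deviation from each gene's mean over the 8 arrays), with TCL1 and ROR1xTCL1 arrays in 2 colours and a marker shape per array letter. Granulocyte markers are high on TCL1 arrays a (2.70) and c (1.26), and erythroid markers on ROR1xTCL1 array a (1.80).

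None of the 5 B cell lists was called. The B cell marker list had 11 of 19 genes above 0 and 8 below, with a median of 0.03 (camera adjusted p = 0.862). The low-affinity IgE receptor Fcer2a differed by 0.42 ± 0.33 and the adaptor Blnk by -0.14 ± 0.11 (SE). Of the B cell receptor signalling list 10 of 23 were above 0 (adjusted p = 0.988), and Cd79a, its signalling chain, read 11.68 ± 0.11 in ROR1xTCL1 and 11.80 ± 0.08 in TCL1 (SD, n = 4 each). Of the list of B-1 cell and chronic lymphocytic leukemia genes 9 of 20 were above 0 (adjusted p = 0.862), and Cd5, the surface marker of both, differed by -0.19 ± 0.12 (SE). Germinal centre genes had 5 of 10 above 0 (adjusted p = 0.739), with Bcl6 at 0.45 ± 0.22 and Rgs13 at -1.35 ± 0.91 (SE). Plasma cell genes had 9 of 12 above 0 (adjusted p = 0.448).

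Lists tied to ROR1 and its reported partners were not called. In the non-canonical Wnt and ROR signalling list 17 of 23 were below 0 (camera adjusted p = 0.649). In the canonical Wnt list 8 of 13 were below 0 (adjusted p = 0.649). Its Wnt inhibitors Apcdd1 and Notum differed by -0.60 ± 0.17 and 0.36 ± 0.16, but by -0.04 ± 0.10 and -0.05 ± 0.12 with gene values made from probe sets (SE). The AKT pathway list had 10 of 19 above 0 (adjusted p = 0.649). Negative regulators of AKT had 10 of 12 above 0, among them the PP2A subunits Ppp2r1b at 0.33 ± 0.20 and Ppp2r1a at 0.15 ± 0.14 (SE; adjusted p = 0.0929). Dual-specificity and tyrosine phosphatases had 8 of 17 above 0 (adjusted p = 0.862), with Dusp7 at 0.54 ± 0.34 (SE). NF-kB targets had 6 of 18 above 0 (adjusted p = 0.837). In the STAT3 and cytokine feedback list Socs1 differed by -0.38 ± 0.13 and Il21r by -0.49 ± 0.21 (SE; adjusted p = 0.448).

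Other cell types and processes were not called either. T cell markers had 14 of 19 above 0 (camera adjusted p = 0.512) with Cd3g at -0.68 ± 0.33 (SE), and natural killer markers had 3 of 12 above 0 (adjusted p = 0.512). Monocyte and macrophage markers had 16 of 18 below 0 (adjusted p = 0.448), erythroid markers 9 of 13 below 0 (adjusted p = 0.862), with Alas2, of haem synthesis, at -0.65 ± 0.81 (SE). Dendritic cell, megakaryocyte and stromal markers had adjusted p = 0.837, 0.739 and 0.739. The BCL2 family and apoptosis list had 14 of 20 above 0 (adjusted p = 0.289), and its score was the only one with an exact 2-sided permutation p of 0.0286, the smallest 4 against 4 arrays can give (adjusted over the lists, 0.99). The p53 target, interferon and antigen presentation lists had adjusted p = 0.377, 0.933 and 0.649. Glycolysis, oxidative phosphorylation and ribosomal protein lists had adjusted p = 0.448, 0.377 and 0.301. Of the glycolysis and ribosomal protein genes written, only 14 of 20 and 14 of 28 were measured. The ribosomal genes Rps18, Rps24 and Rpl4 differed by 0.37 ± 0.18, 0.51 ± 0.28 and 0.47 ± 0.29 (SE). With gene values made from probe sets they differed by -0.08 ± 0.12, -0.11 ± 0.11 and 0.01 ± 0.14 (SE). Immediate early genes, hypoxia, and chemokine receptors and adhesion had adjusted p = 0.837, 0.837 and 0.739, the last with Ccr6 at 0.82 ± 0.32 (SE). Stem cell genes, Notch signalling and epigenetic regulators had adjusted p = 0.837, 0.512 and 0.649. Lipid and cholesterol synthesis had 11 of 18 above 0 (adjusted p = 0.161), with the farnesyl diphosphate synthase gene Fdps at 0.85 ± 0.31 (SE), and at 0.07 ± 0.13 (SE) with gene values made from probe sets. Over all 38 lists, 0 were called with an estimated correlation and 0 by fry, and in 33 lists the estimated correlation exceeded the preset 0.01. For 3 lists, which include the germinal centre list, camera's direction was opposite to the sign of the mean difference.

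At probe set level, 0 of 1236087 probe sets passed (limma, smallest adjusted p = 0.931), with 40767 (3.30%) at an unadjusted p under 0.05. With trend and robust estimation 1 passed, the unnamed probe set 5220710, lower by -2.89 ± 0.27 (SE, adjusted p = 0.0386). Without ROR1xTCL1 replicate 1, Ror1 probe set 5507566 passed over all probe sets (3.75 ± 0.29 SE, adjusted p = 0.0484), with the unnamed probe set 5169078 (4.82 ± 0.32 SE, adjusted p = 0.0168). Without TCL1 replicate 4, the unnamed probe sets 4943094 and 5065489 passed, at -4.44 ± 0.30 and -5.60 ± 0.40 (SE, adjusted p = 0.0259 for each).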

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

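In groups of 4 arrays, a value was singled out where its gap to the nearest other array exceeded Dixon's 95% critical share of the group's range. Of 366 groups examined over the named genes and list scores, 19 were singled out, and chance gives about 1 in 20, or 18.3. Apart from the Y-linked genes, which the Xist values tie to male animals, the explanations of these were not tested. In the next paragraph others, high, low, highest and lowest refer to the arrays of the same group.

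The clearest were the Y-linked genes on TCL1 array c, the only array of its group with high values: Ddx3y at 7.29 (others 2.43 to 2.80), Kdm5d at 6.59, Eif2s3y at 7.97, and the score of the sex-linked list at 3.12. ROR1xTCL1 array a stood apart for the haemoglobin gene Hbb-b1 at 11.18 (others 8.65 to 8.96), Birc5 at 6.80 (others 5.53 to 5.73), Il21r at 7.56 and Ror2 at 4.66. TCL1 array c was also high for Uhrf1 (7.90), and its B cell receptor signalling score was 0.0642. TCL1 array d was highest for Ror1 (4.03), Tcl1 (4.05) and the prolyl hydroxylase P4ha2 (3.73). ROR1xTCL1 array b was lowest for Stat2 (6.07) and the DNA methyltransferase Dnmt1 (7.40). ROR1xTCL1 array c was high for P4ha1 (7.87), low for the activation marker Cd83 (8.85) and lowest in the MYC and ribosome biogenesis score (-0.0732). ROR1xTCL1 array d was high for Tcl1b4 (4.16).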

How the results depend on the processing

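The count of changed genes was 0 under every setting run. Genes at an unadjusted p under 0.05 (268 in the report) numbered 423 with gene values made from probe sets, 100 without dim genes, which also tests fewer genes, and 225 to 426 with 1 array left out. Of 144 named genes, 24 changed sign under at least 1 setting. The 19 named for small p were picked for no overlap, so leaving out an array cannot turn their sign. With gene values made from probe sets, 28 of 137 named genes kept under 50% of their difference or turned, and of 26 at an unadjusted p under 0.05, 17 stayed under it. Of the 38 lists tested (5 called in the report), at the preset correlation 1 was called with gene values made from probe sets, 2 after a further quantile normalization, 2 without dim genes, and 1 to 6 with 1 array left out. Adjusted p for cell cycle, DNA replication, MYC and unfolded protein response was 0.0779, 0.0779, 0.081 and 0.271 with values from probe sets. For the last 3 it was 0.114, 0.141 and 0.173 after quantile normalization and 0.0626, 0.0998 and 0.0998 without dim genes. Centring ended the unfolded protein response call (0.0645). With camera's estimated correlation 0 lists were called (adjusted p = 0.914 for each of the 5), with fry 0 (0.966) and with the permutation test of scores 0 (0.99). The permutation test cannot give a p below 0.0286. Adjusted over 38 lists, 1 list alone could not pass it, so its count of 0 decides little. With 1 array left out, adjusted p ran from 6.32e-12 to 0.716 for the granulocyte list, 1.27e-07 to 0.994 for cell cycle, 1.06e-08 to 0.994 for DNA replication, 0.00456 to 0.249 for MYC and 6.61e-05 to 0.885 for the unfolded protein response. Cell cycle turned lower without ROR1xTCL1 array a (0.994). The cause was not tested for these settings. The Ror1 probe sets past the threshold over the gene alone (4) numbered 3 to 5 under every setting, and the differences of 5507566, 5612493 and 5320447 stayed within 3.06 to 3.75, 3.21 to 4.19 and 1.98 to 2.47. Probe sets past the threshold over all numbered 1 with trend and robust and 0 to 2 with 1 array left out; at an unadjusted p under 0.05 they numbered 20068 without dim probe sets and 36912 to 58979 with 1 array left out.

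The following were chosen after seeing the data, apart from the block on probe sets. Deviations from the group means correlated over 0.1 across genes in 3 of the 4 pairs of the same number (r of -0.0061 to 0.233). Pairing was taken to need all 4, so the block was kept out of the report. 2 of 4 TCL1 arrays correlated best with their own number by these deviations and 3 of 4 by probe set values, a hint from the data and not the design. The highest r by these deviations, 0.317, joined unlike numbers, TCL1 replicate 4 and ROR1xTCL1 replicate 2. With the replicate block 0 probe sets passed, as without it. On gene values made from probe sets the replicate block gave 0 genes, as without it, and 574 at an unadjusted p under 0.05 (423 without). It called 3 lists (1 without): cell cycle went from 0.0779 to 0.019 and DNA replication from 0.0779 to 0.0433, with MYC at 0.119 and unfolded protein response at 0.323. These calls are at the preset correlation; with an estimated one 0 lists were called on these values, with the block (0.957 for each of the 5) and without it (0.993). With the Y-linked genes as a covariate 1 list was called, with cell cycle at 0.0672, DNA replication at 0.163, MYC at 0.0594 and unfolded protein response at 0.0594. Without TCL1 arrays a and c, 622 genes had an unadjusted p under 0.05 and 7 lists were called. Cell cycle (3.22e-14) and DNA replication (2.91e-12) stayed higher in ROR1xTCL1 with smaller p, MYC stood at 0.205, and the granulocyte (3.22e-14), natural killer (0.0481) and interferon (0.0454) lists turned higher in ROR1xTCL1. With an estimated correlation the same 6 arrays gave 0 lists: 0.57 for the granulocyte list, again higher, 0.593 for cell cycle, 0.57 for DNA replication, 0.808 for MYC and 0.841 for unfolded protein response. TCL1 arrays a and c had the 2 highest scores of their group for the cell cycle, DNA replication, granulocyte, natural killer and interferon lists. Leaving them out lowers the TCL1 mean of these lists by construction, so their smaller p or turn upward decides nothing. Dim signals limit 17 of the 19 genes named for small p, which averaged under 5 on the log2 scale. Other named genes, such as Apcdd1, Fdps and Ccr6, averaged under 5 as well.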

Other observations

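Immunoglobulin probe sets differed between individual arrays. Of 152 immunoglobulin probe sets, 16 (10.5%) were more than 3 log2 units higher on 1 array than on every other, against 0.0358% of all probe sets. ROR1xTCL1 replicate 2 read 12.57, 12.64 and 12.46 at 3 Igk probe sets where the other arrays read at most 8.60, and 8.33 at an Igh-VS107 probe set where they read at most 1.91. ROR1xTCL1 replicate 3 read 12.54 and 12.36 at 2 Igk-V21-4 probe sets (others at most 8.80), and 10.67 to 11.70 at 4 probe sets of Ighg1, a constant region used after class switching (others at most 7.17). TCL1 replicates 1 and 3 had 1 such Igh probe set each, at 9.02 and 6.78. Probe sets annotated to Igk-C differed from each other: 5227529 read 13.19 ± 0.19 in ROR1xTCL1 and 13.18 ± 0.21 in TCL1 (SD, n = 4 each), while 4485053 read 6.55 ± 0.37 and 9.26 ± 0.66 and 4464515 read 7.95 ± 0.76 and 9.84 ± 0.79, with no overlap between the groups. Probe set 5295157 differed by -2.87 ± 1.04 (SE), with overlap. Probe sets 4603367 and 5265452, annotated to other genes as well, differed by -2.07 ± 0.34 and -1.84 ± 0.49 (SE), without overlap. None of these Igk-C probe sets passed over all probe sets (limma adjusted p = 1.0). These probe sets were chosen after their values were seen.

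Genes other than immunoglobulins also stood out on single arrays. Whether the leukemia cells or other cells of the sample expressed them was not tested. On ROR1xTCL1 array a, Trim29 read 11.61, Nectin1, an adhesion molecule, 10.13 (others at most 6.73) and the potassium channel gene Kcnj1 8.92 (others at most 5.86). On ROR1xTCL1 array b, the B cell chemokine Cxcl13 read 9.10 (others at most 5.95), the receptor tyrosine kinase Met 8.34 (others at most 5.19) and the acute phase gene Saa3 7.74 (others at most 4.16). Sall3 read 7.71 on ROR1xTCL1 array c and Epb41l4b 7.79 on TCL1 array b. These 8 were all the genes that exceeded every other array by more than 3 log2 units, and they were chosen after their values were seen.

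Of the tests below, the splits for genes and for the number of lists and the tests that leave out arrays were chosen only after the result, or the array scores behind it, was seen. The counts of 0 genes and 0 probe sets past the threshold are reached by all 35 splits of the 8 arrays into 4 and 4 whatever the values, so they decide nothing about chance; the highest other counts were 0 and 2. Chance could not be excluded for the number of lists or for each called list. For the counts at an unadjusted p under 0.05 the test counted splits with as many or more, so it cannot judge counts that are low. As many lists as the 5 called were called in 26 of 35 splits, with up to 12. Camera p-values as small as the real one came, over this exact enumeration of splits, in 15 of 35 splits for the granulocyte list (real p = 7.62e-06, smallest other 2.60e-19), 17 for cell cycle (0.000287, other 7.14e-31), 17 for DNA replication (0.00193, other 1.17e-18), 4 for MYC (0.00433, other 8.34e-05) and 16 for unfolded protein response (0.00582, other 5.38e-14). For probe sets, 34 of 35 splits gave as many at an unadjusted p under 0.05 as the real 40767 (highest other 95610).

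The real split had the fewest genes at an unadjusted p under 0.05, 268. That 35 of 35 splits gave as many follows from this and does not test the low count. The highest other, 1950, set arrays a and c of both groups against b and d of both. Every split but the real one mixes the genotypes, so that the highest does so was fixed in advance and shows nothing. A hypothesis was that mice of both sexes in each group widen the spread. With the Y-linked genes as a covariate 1.81% of genes had an unadjusted p under 0.05, still under the 3% set as its bound, which argues against sex as the whole of it. What else separates the arrays, such as the stage of each leukemia, stays open and untested.

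The granulocyte shift may come from granulocyte-lineage cells in TCL1 arrays a and c. A separate list of 20 granulocyte markers, 0 of them in another list, was written before this test, though the 2 arrays were picked from their scores; 2 of its genes lay above the median gene on all 8 arrays. Of the 16 measured, 7 (43.8%) were higher on both arrays than on each of the other 6. Among them were Anxa1 at 8.32 and 6.32 (others at most 4.80) and Ms4a3 at 6.26 and 5.81. Chance gives 3.57%, but only for arrays not picked by a score and for unrelated markers. The score of the 16 markers was 1.51 on array a but 0.175 on array c, and at most 0.06 on the other 6. The share of 43.8% fell short of the 50% set for the explanation and lay above the 10% set against it. Monocyte, T cell, natural killer and dendritic cell scores were highest on array a but not on array c. The source of the signal therefore cannot be told apart from a change in the leukemia cells. That the list turned higher in ROR1xTCL1 without these 2 arrays (adjusted p = 3.22e-14 with a preset correlation, 0.57 with an estimated one) adds nothing, since they were picked for its highest scores.

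The higher cell cycle genes could reflect erythroid precursors in ROR1xTCL1 array a, which had the highest erythroid score, 1.80. Without that array the list turned lower (adjusted p = 0.994), which decides nothing, since the array also had the highest cell cycle score, 0.58. The call ended as well without TCL1 array b (0.378), TCL1 array d (0.782) or ROR1xTCL1 array d (0.114). Erythroid cells, a leukemia that itself divides faster, a part of the genotype and chance all stay open.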
